A study of Mus musculus with 8 samples.

How the data were processed

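Total RNA was measured in 8 samples of lumbar intervertebral discs from female BALB/c mice, 3 from naive and 5 from immunized mice. Each sample was RNA from 6 pooled discs (levels L1 to L6), per the labels' protocols. The immunized mice received cartilage proteoglycan containing 100 µg of protein in 2 mg of the adjuvant dimethyldioctadecylammonium bromide on days 0, 21 and 42, and the naive mice were matched for age. Biotinylated cRNA made from 2 to 5 µg of total RNA was hybridized to Affymetrix arrays, per the labels. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. The descriptions of naive replicate 3 and immunized replicate 1 each join 2 sample numbers. Whether these are pools of 2 mice is not given in the sources used here, so neither is the number of mice.

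The authors deposited 1 log2 value per probe set and array, made by robust multi-array averaging (RMA), per the submitters' processing notes; the software version is not given in the sources used here. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale. The log base is that of RMA and is not stated in the table. The values show a further step that the labels do not record: the median of every probe set over the 8 arrays is 0 to within 5.0e-07, so each deposited log2 value is a difference from that median. Differences between groups are unaffected by this centring. Absolute signal is lost, and no level of one gene can be set against that of another. The spacing of the printed numbers still shows a coarse level for the lowest array of each probe set. It was 8 or more (log2) for 32.4% of the 45101 probe sets, from 4 to 8 for 57.1% and below 4 for 10.6%. Array medians lay between -0.012 and 0.016. No scan date or batch was available, and the number of arrays limits the precision.

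Genes were named through the platform's annotation, with symbols looked up by gene identifier in a RefSeq table of assembly GRCm38.p6. A single gene was named by 34958 probe sets, several genes by 932 and no gene by 9211. The lookup changed no symbol, and 162 symbols had no match and were kept. The 64 control probe sets were left out. The original plan measured a gene by its probe set with the highest mean, which the centring rules out. In its place, by a choice also listed in advance, each of 18193 genes was measured by the mean of all probe sets that name it alone. Among called genes with several probe sets (855), 5 had a probe set that moved the other way at an unadjusted p under 0.05.

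Immunized mice were compared with naive mice in limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors beside log2 differences are limma's standard errors (SE), for 5 immunized against 3 naive samples. On simulated data with the same 18193 genes and the same spread, the immunized against naive test called 82% of genes changed by 1 and 96% of those changed by 2 on the log2 scale. In that simulation 5 of 183 calls were false. Its noise was drawn independently for each gene and with the same spread in all arrays. Real genes vary together, so these rates need not hold for the real data.

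In advance, 41 gene lists were fixed, 18 of pathways or processes and 23 of cell type markers. Each list was tested with limma's camera against all other genes, with a preset correlation between genes of 0.01 and adjustment over the 41 lists. Camera was repeated with a correlation estimated from the data. Fry, a rotation test of whether a list moves on balance one way, and an exact two-sided permutation test of the list mean over the 56 splits of the samples into 3 and 5 were run beside it. The smallest p that this permutation test can give is 0.0357. Members of a list were counted at an adjusted p under 0.05 over all genes and, separately, adjusted over the list alone.

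The genes named were chosen by a rule fixed in advance. It takes the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups (provisional names passed over), up to 4 members of each list with the largest moderated t, and always Acan, Tnf, Il1b, Il6, Il17a, Il23a and Ifng. Other genes are said to have been chosen after their values were seen, or are further members of a fixed list that passed a test.

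Before the data were examined, other settings were listed: quantile normalization, median centring of arrays, omission of probe sets ending in _x_at and _s_at, a trended and robust variance model, array weights, the replicate number as a block, omission of both samples with joined numbers, each sample left out in turn, other thresholds, and all probe sets tested singly. A listed filter on the mean level was not run, because the centring removed the level. The settings added after the data were seen were the probe sets of a gene's highest level class, omission of probe sets with an array below 4 (log2), the mean of the erythroid markers as a covariate, and omission of naive replicate 1 with immunized replicates 3 and 5. Figures were drawn with matplotlib 3.10.9. No coordinates are given, because no build is named for the arrays.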

Results

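Gene expression was measured in intervertebral discs from mice with proteoglycan-induced spondylitis, in which immunization of BALB/c mice with cartilage proteoglycan leads to autoimmune inflammation of the spine, and in discs from naive mice. The comparison, 5 immunized against 3 naive samples, asks which genes differ in the discs of mice with spondyloarthropathy. Values are log2 expression relative to the median of the 8 arrays, so a difference of 1 is a doubling. The first principal component held 52.2% of the variance and parted the groups, with immunized replicate 2 (-5.77) nearest to the naive samples (-32.2 to -28.1). The second component held 19.7% and set naive replicate 1 (32.1) apart from the other naive samples (-7.53 and -7.07).

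Discs of immunized mice had higher expression of several genes of myeloid cells, acute phase proteins, chemokines and immunoglobulins. They had lower expression of several genes of cartilage matrix, of the keratins Krt19 and Krt20 and of the clock transcription factors Dbp and Nr1d1. Of 18193 genes, 812 were higher and 851 lower in immunized mice. A difference of at least 1 on the log2 scale was reached by 239 of the higher and 96 of the lower genes. In 790 of the higher genes all 5 immunized samples lay above all 3 naive samples, and in 844 of the lower genes all lay below. Over all genes, 23.4% did not overlap, against 3.57% on average over all splits of the samples into 3 and 5. Genes vary together, so a single split can lie far from that average. At an unadjusted p under 0.05 in limma, 2346 of the 18193 genes were higher and 3311 lower. The unadjusted counts given below for lists have to be read beside this base. Higher genes made up 48.8% of the calls, and 59.5% (540 higher, 368 lower) after quantile normalization of the deposited values. That setting acted on values that RMA had already quantile-normalized and that were then centred per probe set. It evens out the spread of the arrays about the median (SD 0.41, 0.29 and 0.29 in naive, 0.21 to 0.32 in immunized samples). This spread can hold part of the group difference, so a call lost in that setting can reflect the step itself. Without both samples whose descriptions join 2 numbers, no call remained in limma (1621 higher and 2173 lower at an unadjusted p under 0.05). The number of calls depended on single samples. It was 374, 21 and 176 without naive replicates 1, 2 and 3, and 148, 3003, 758, 868 and 394 without immunized replicates 1 to 5, against 1663 with all samples.

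**Figure D1:**
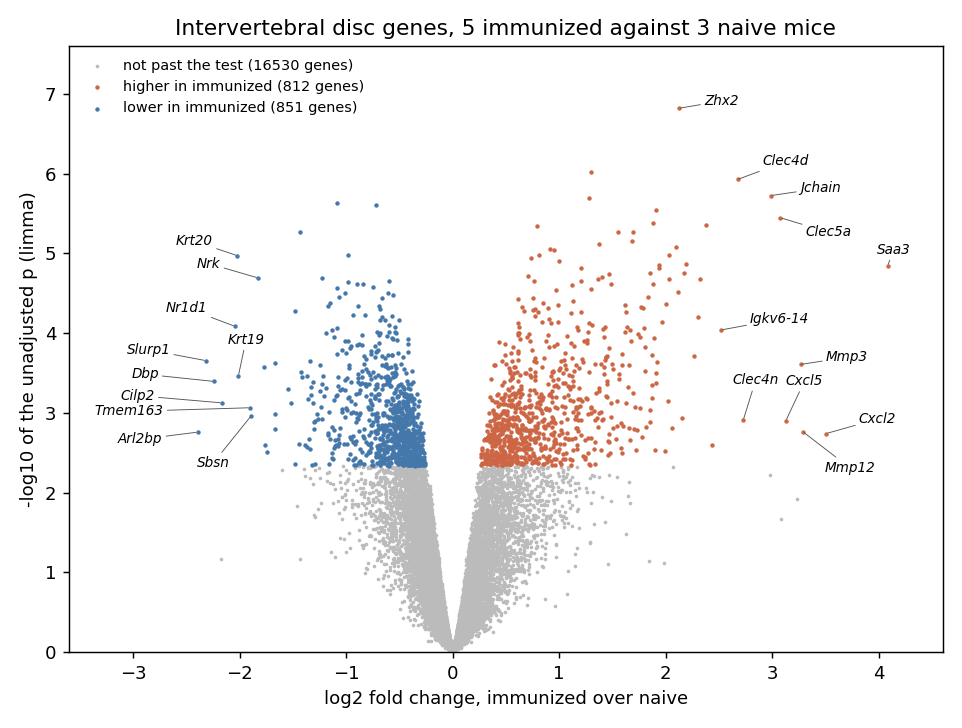
Difference between immunized and naive discs (x axis, log2) against the -log10 of limma's unadjusted p (y axis) for each of 18193 genes. Points in orange (812) and blue (851) passed an adjusted p of 0.05; the 10 largest non-overlapping changes in each direction are named, and Zhx2, with the lowest p, was named after its value was seen.

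Among genes taken by the naming rule, each measured by the mean of its probe sets, the largest rise was that of Saa3. It encodes the acute phase protein serum amyloid A3. Saa3 was higher by 4.08 ± 0.48 (SE, adjusted p = 0.00902), or 17.0-fold. Next came Cxcl2 (3.51 ± 0.80) and Cxcl5 (3.13 ± 0.68), chemokines that attract neutrophils, and the matrix metalloproteinases Mmp12 (3.29 ± 0.74) and Mmp3 (3.27 ± 0.56). The C-type lectin receptors Clec5a (3.08 ± 0.31), Clec4n (2.73 ± 0.59) and Clec4d (2.68 ± 0.23), carried by myeloid cells, rose. Jchain, whose product joins polymeric IgM and IgA, rose by 2.99 ± 0.27, and the immunoglobulin kappa variable gene Igkv6-14 by 2.52 ± 0.38. Probe sets for immunoglobulin variable genes can bind transcripts of related genes. Within this set of 10 rises, Cxcl2 and Mmp12 varied most among the immunized samples (SD 1.63 and 1.51) and Clec4d much less (SD 0.45). Of these 10 genes, 5 passed without naive replicate 1, 3 without naive replicate 2 (Clec5a, Jchain and Clec4d), 5 without naive replicate 3, 6 without immunized replicate 1, 9 without immunized replicate 4 and 6 without immunized replicate 5. Quantile normalization ended the calls of Mmp12 and Cxcl5.

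By the same rule, the largest fall was that of Arl2bp, which encodes a protein that binds the small GTPase ARL2, at -2.39 ± 0.54 (adjusted p = 0.0348). Immunized replicate 5 (1.20) lay far above the other immunized samples in Arl2bp and next to the naive samples. Slurp1, a secreted protein of epithelia, differed by -2.32 ± 0.39, and Sbsn, another epithelial protein, by -1.89 ± 0.40. Dbp (-2.24 ± 0.41) and Nr1d1 (-2.05 ± 0.30), both transcription factors of the circadian clock, fell, as did Cilp2, a cartilage matrix protein (-2.17 ± 0.43). The keratins Krt20 (-2.02 ± 0.23) and Krt19 (-2.01 ± 0.36) fell, Krt19 being a marker of the nucleus pulposus. Tmem163 (-1.90 ± 0.39) and the kinase gene Nrk (-1.82 ± 0.22) completed the 10. Of these 10 genes, 4 passed without naive replicate 1, 0 without naive replicate 2 in limma, 2 without naive replicate 3, and 3, 7, 8 and 8 without immunized replicates 1, 3, 4 and 5. Quantile normalization ended the call of Cilp2, and the trended and robust model those of Krt20 and Nrk. Without naive replicate 2 only 21 genes passed in all, and 1971 higher and 2658 lower genes had an unadjusted p under 0.05.

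Of the 41 fixed lists, camera with the preset correlation found 18 shifted higher, 9 lower and 14 neither. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.438, and 4 had an unadjusted p under 0.05. Fry called 5 lists higher (Fc receptors and adaptors, acute phase and granule proteins, toll-like receptors and NF-kB, plasma cell, macrophage) and 0 lower. The exact permutation test of list means gave its smallest p, 0.0357, for 16 lists, and an adjusted p of 0.0915 for each. Without both samples with joined numbers camera lost the bone formation (adjusted p = 0.0610), endothelium (0.120), immediate early (0.120), megakaryocyte (0.139), neuron (0.0674) and Schwann cell (0.207) lists, and after quantile normalization the megakaryocyte and neuron lists (0.0574 each). Counting the real split, camera called as many lists higher in 4 of the 56 splits of the samples, and as many lower in 28.

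Lists of innate immunity genes shifted higher by camera (adjusted p = 0.438 for each of the 3 below with an estimated correlation). Of 11 Fc receptors and adaptors, 7 rose (9 adjusted over the list alone), among them the inhibitory IgG receptor Fcgr2b (1.12 ± 0.14), the activating receptor Fcgr3 (1.43 ± 0.21) and the lectin receptor Clec4e (2.38 ± 0.24). Fcgr3 was lowest in immunized replicate 2 (-0.31), apart from the other immunized samples. Of 16 acute phase and granule proteins, 7 rose (15 adjusted over the list alone), including lysozyme Lyz2 (0.91 ± 0.13), Chil1 (1.18 ± 0.18) and orosomucoid Orm1 (1.22 ± 0.20). Of 19 genes of toll-like receptors and NF-kB, 8 rose (10 adjusted over the list alone), including Tlr2 (0.97 ± 0.12), the NF-kB regulator Nfkbiz (0.90 ± 0.14) and the adhesion molecule Vcam1 (0.85 ± 0.17). Lyz2 and Tlr7 (0.62 ± 0.09) were also lowest in immunized replicate 2 among the immunized samples. The probe sets of Tlr7 differed by 1.36, 0.28 and 0.22.

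Among chemokines, 5 of 23 rose (10 adjusted over the list alone), and besides Cxcl2 and Cxcl5 these were the monocyte attractants Ccl6 (1.38 ± 0.26), Ccl8 and Ccl9 (1.89 ± 0.29). Of 21 interferon response genes, 7 rose (12 adjusted over the list alone), with Oas1a at 1.56 ± 0.28, Usp18 at 1.13 ± 0.21, Gbp3 at 0.95 ± 0.17 and Bst2 at 0.84 ± 0.17. Of 14 complement genes, 3 rose: the anaphylatoxin receptors C3ar1 (2.43 ± 0.59) and C5ar1 (1.30 ± 0.30) and the protease C1s1 (1.01 ± 0.24). Adjusted over the list alone, 8 complement genes rose and 1 fell. Of 18 antigen presentation genes, 3 rose (9 adjusted over the list alone), the lysosomal protease Ctss (1.97 ± 0.28), the costimulator Cd86 (0.97 ± 0.19) and the invariant chain Cd74 (0.77 ± 0.18). Naive replicate 1 stood apart in the interferon response mean (-0.10, against -0.54 and -0.62 in the other naive samples and -0.14 in immunized replicate 5) and in antigen presentation (-0.07, against -0.50 and -0.49). After quantile normalization 3 chemokine, 4 interferon response and 1 antigen presentation genes rose, and 0 complement genes passed in limma (7 higher and 1 lower, unadjusted). Each of these 4 lists shifted higher by camera, with an adjusted p of 0.438 with an estimated correlation.

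Of 24 cytokine genes, 3 rose (4 adjusted over the list alone): Il1b (1.90 ± 0.47), its antagonist Il1rn (1.91 ± 0.35) and Tnfsf13b, a B cell survival factor (0.71 ± 0.15). The list shifted higher (adjusted p = 0.438 with an estimated correlation). Il6 differed by 3.23 ± 1.03 but did not pass (adjusted p = 0.0763). Its immunized values ranged widely (SD 2.10, n = 5), although all lay above the naive values. The only probe sets of Il6 and Ifng had an array below 4 (log2), so both genes drop out where such probe sets are omitted. The differences in Tnf (0.18 ± 0.11), Il17a (-0.05 ± 0.09), Il23a (-0.04 ± 0.09) and Ifng (-0.11 ± 0.08) did not pass. Over the 8 immune lists, 43 of 146 distinct genes rose and 0 fell in limma, while 89 higher and 2 lower had an unadjusted p under 0.05. The number called was 2 without naive replicate 2, 6 without naive replicate 3, 16 without immunized replicate 1 and 26 without immunized replicate 5.

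**Figure D2:**
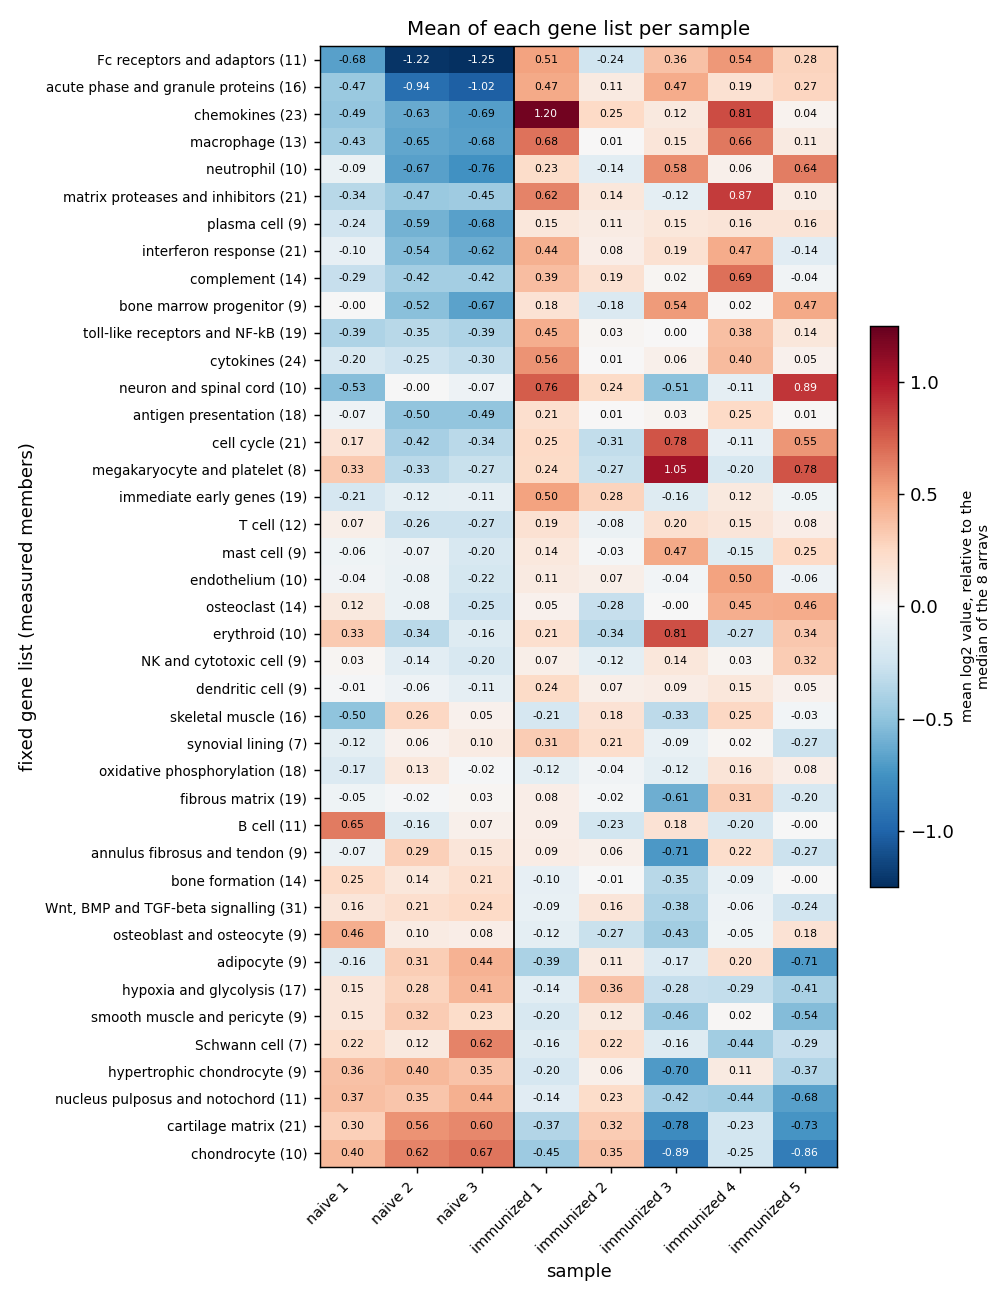
Mean log2 value of the measured members of each fixed list (rows, number of members in parentheses, ordered by the difference between groups) in each sample (columns), relative to the median of the 8 arrays. Fc receptors and adaptors differed most upward (naive mean -1.05, immunized mean 0.29) and chondrocyte genes most downward (0.57 and -0.42), while erythroid, megakaryocyte and cell cycle genes were highest in immunized replicates 3 and 5.

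Several markers of macrophages, neutrophils and plasma cells rose in immunized discs. Of 13 macrophage markers 6 rose, with the integrin Itgam at 1.81 ± 0.29, the surface receptor Adgre1 at 1.45 ± 0.27, Mpeg1 at 1.39 ± 0.24 and the mannose receptor Mrc1 at 0.72 ± 0.14. Adjusted over the list alone, 8 rose and 1 fell. Of 10 neutrophil markers 3 rose (9 adjusted over the list alone): the chemokine receptor Cxcr2 (1.54 ± 0.34), the collagenase Mmp8 (1.47 ± 0.35) and the calprotectin subunit S100a9 (0.40 ± 0.09). Of 9 plasma cell markers 3 rose (4 adjusted over the list alone), namely Jchain, Ighm (1.71 ± 0.38) and Xbp1 (0.26 ± 0.07). The 11 probe sets of Ighm disagreed, from -0.26 to 4.85. Those of Xbp1 ranged from 0.14 to 0.51. The neutrophil means of the groups overlapped, naive replicate 1 (-0.09) lying above immunized replicate 2 (-0.14) and apart from the other naive samples (-0.67 and -0.76). After quantile normalization 5 macrophage and 1 plasma cell marker rose, and 0 neutrophil markers passed in limma (9 higher, unadjusted). All 3 lists shifted higher by camera, with an adjusted p of 0.438 with an estimated correlation.

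Of 12 T cell markers, Cd3g rose (1.03 ± 0.23) and Cd8b1 fell (-0.39 ± 0.08), and adjusted over the list alone 4 rose and 1 fell. Of 9 mast cell markers, Hdc, the enzyme that makes histamine, rose (1.37 ± 0.26), while the proteases Tpsab1 (-0.54 ± 0.11) and Cma1 (-0.61 ± 0.14) fell; adjusted over the list alone 4 rose and 3 fell. No marker passed limma's test over all genes among 11 B cell genes (3 lower at an unadjusted p under 0.05, led by Cd79a at -0.83 ± 0.26), 9 dendritic cell genes (2 higher, unadjusted) or 9 NK and cytotoxic cell genes (4 higher, unadjusted; 1, Gzmb, adjusted over the list alone). Adjusted over the list alone, 0 B cell and 0 dendritic cell genes passed. None of these 5 lists shifted by camera, the adjusted p lying between 0.0716 for NK cells and 0.599 for mast cells. The T cell list shifted higher without naive replicate 1 (adjusted p = 0.0467) and the B cell list lower without naive replicate 2 (0.0228), against 0.217 and 0.287 with all samples; with an estimated correlation the adjusted p in these settings was 0.444 and 0.502. The median B cell difference was -0.29 with all samples, but 0.057 without naive replicate 1 and 0.029 with array weights.

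Genes of dividing and immature marrow cells were high in some samples of both groups. The erythroid mean was 0.33 in naive replicate 1, 0.81 in immunized replicate 3 and 0.34 in immunized replicate 5, and lay between -0.34 and 0.21 in the other samples. Megakaryocyte markers and cell cycle genes were also highest in immunized replicates 3 and 5 (1.05 and 0.78 for megakaryocytes; 0.78 and 0.55 for the cell cycle). Neutrophil markers were highest in the same 2 samples (0.58 and 0.64). Of 21 cell cycle genes Mki67 rose (0.95 ± 0.23), and 0 passed adjusted over the list alone (5 higher, unadjusted). The list shifted higher by camera, with an adjusted p of 0.502 with an estimated correlation. In limma's test over all genes 0 of 9 bone marrow progenitor genes passed (6 higher, unadjusted; 5 adjusted over the list alone; adjusted p = 0.438 with an estimated correlation), and 0 of 8 megakaryocyte genes (1 higher, unadjusted; 0 adjusted over the list alone; adjusted p = 0.594 with an estimated correlation), although camera called both lists higher. The megakaryocyte call ended without naive replicate 2 (adjusted p = 0.174), naive replicate 3 (0.155), immunized replicate 3 (0.147) or immunized replicate 5 (0.118), and with arrays centred on their medians (0.0534). None of 10 erythroid genes passed in limma (0 at an unadjusted p under 0.05), and that list did not shift (adjusted p = 0.217), but did without naive replicate 1 (0.0240; adjusted p = 0.503 with an estimated correlation).

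Over these 12 lists of blood cells and the cell cycle, 15 of 129 distinct genes rose and 3 fell (8 and 2 after quantile normalization). The number called was 10, 1 and 2 without naive replicates 1, 2 and 3, and 3, 34 and 6 without immunized replicates 1, 2 and 5. With naive replicate 1 and immunized replicates 3 and 5 left out, a choice made after the data were seen, 173 genes were higher and 45 lower over all genes. Of the genes in the 8 immune lists 20 rose in that setting and 0 fell in limma.

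Several cartilage genes fell in immunized discs. All 21 cartilage matrix genes had a negative difference, and 6 fell (12 adjusted over the list alone), among them the type IX and XI collagen genes Col9a1 (-1.75 ± 0.44), Col9a3 (-0.94 ± 0.22) and Col11a2 (-1.26 ± 0.27), the proteoglycan gene Snorc (-1.30 ± 0.29) and Sox9, the transcription factor of chondrocytes (-0.83 ± 0.19). Acan, which encodes aggrecan, the core protein of the immunizing proteoglycan, differed by -0.95 ± 0.30 and did not pass (adjusted p = 0.0781). The 10 chondrocyte markers overlap that list, with 3 lower (7 adjusted over the list alone). Of 9 hypertrophic chondrocyte markers 3 fell (6 adjusted over the list alone), namely Ihh (-0.93 ± 0.24), the parathyroid hormone receptor Pth1r (-0.78 ± 0.19) and the phosphatase Alpl (-0.68 ± 0.16). Of 11 nucleus pulposus and notochord markers Krt19 fell (7 adjusted over the list alone). After quantile normalization 1 cartilage matrix gene, 1 chondrocyte and 1 nucleus pulposus marker fell, and 0 hypertrophic chondrocyte markers passed in limma (6 lower, unadjusted). In limma 0 cartilage matrix genes passed without naive replicate 1, 2 or 3 or immunized replicate 1, 4 or 5 (17, 12, 11, 12, 13 and 14 lower, unadjusted). All 4 lists shifted lower by camera, with an adjusted p of 0.438 with an estimated correlation. Immunized replicate 2 lay with the naive samples in the cartilage matrix mean (0.32, against 0.30 to 0.60 in naive and -0.78 to -0.23 in the other immunized samples).

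Fibrous matrix genes did not move as a group. None of 19 passed limma's test (2 higher and 3 lower, unadjusted; 0 adjusted over the list alone), Lum (0.73 ± 0.20, adjusted p = 0.0519) and Eln (-0.46 ± 0.16) having the largest moderated t on each side, and the list did not shift (adjusted p = 0.695). Of 9 annulus fibrosus and tendon markers 0 passed in limma (1 lower, unadjusted; 0 adjusted over the list alone), with Fmod at -0.74 ± 0.22. That list did not shift (adjusted p = 0.217). Of 21 matrix proteases and inhibitors 5 rose and 1 fell, with the same counts adjusted over the list alone. The protease genes Mmp3, Mmp12, Mmp8 and Ctss and the urokinase receptor Plaur (1.02 ± 0.17) rose, and the metalloproteinase inhibitor Timp2 fell. The list shifted higher (adjusted p = 0.438 with an estimated correlation). Of 88 distinct matrix, protease and disc cell genes 5 rose and 11 fell, but 3 rose and 2 fell after quantile normalization (10 higher and 31 lower, unadjusted). The number called was 2, 0 and 0 without naive replicates 1, 2 and 3, and 1, 37, 7 and 4 without immunized replicates 1, 2, 4 and 5. Without naive replicate 2, 7 higher and 26 lower genes had an unadjusted p under 0.05 in limma, and without naive replicate 3, 8 and 25.

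**Figure D3:**
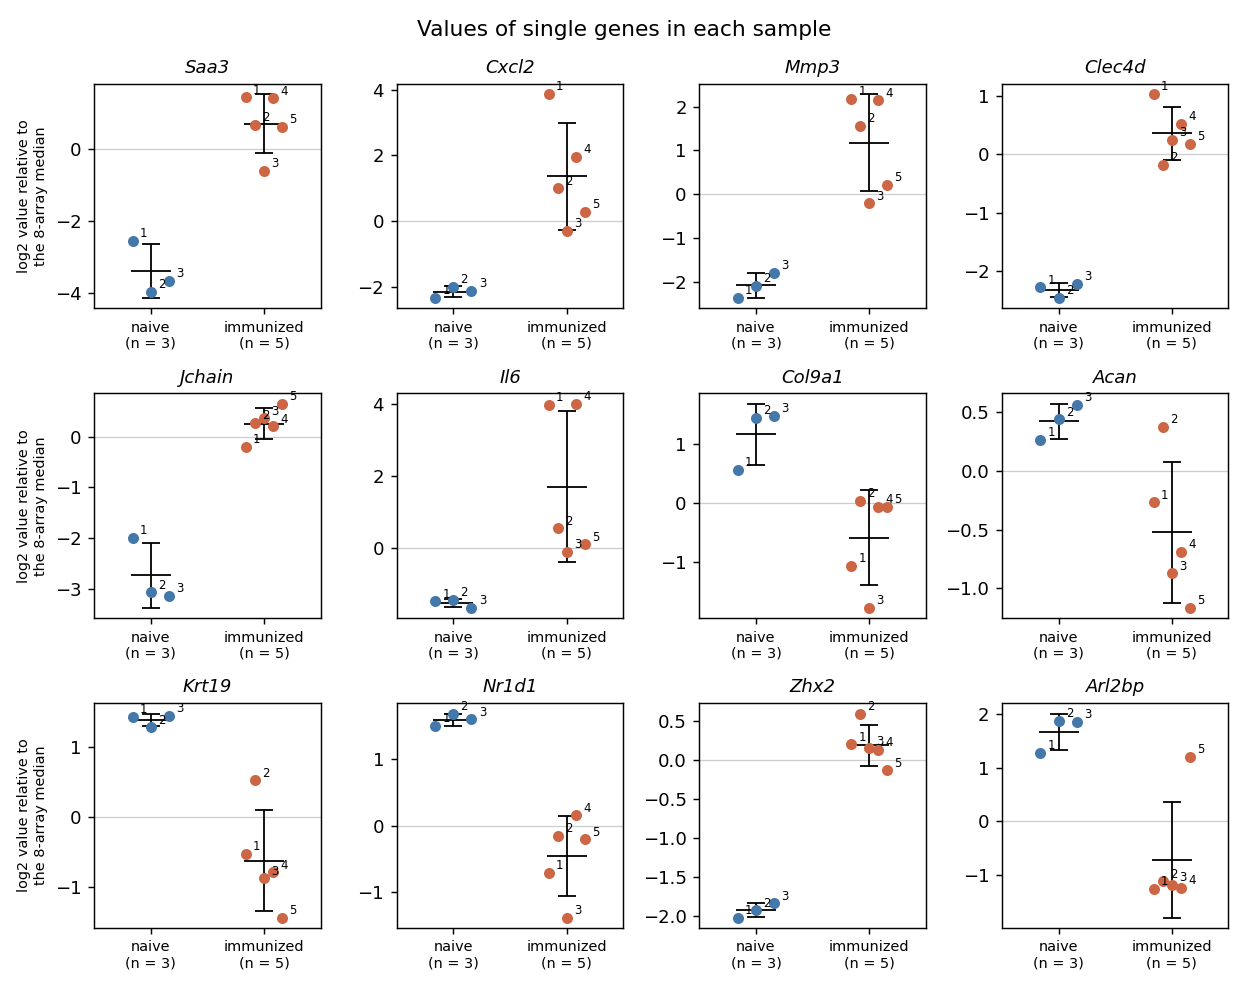
Values of 12 genes in each sample (points, numbered by replicate; y axis, log2 relative to the median of the 8 arrays), with the mean and SD of the 3 naive (blue) and 5 immunized (orange) samples. The groups did not overlap in Saa3, whereas in Acan immunized replicate 2 lay among the naive samples and in Arl2bp immunized replicate 5 lay near them; Zhx2 was chosen after its values were seen.

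Among 14 bone formation genes 3 fell (4 adjusted over the list alone): the transcription factor Dlx5 (-0.97 ± 0.15), Alpl and Pth1r. Alpl and Pth1r are also among the hypertrophic chondrocyte markers above. Another list shares 9 of these 14 genes, and 7 of the 9 osteoblast and osteocyte genes below are shared as well. The list shifted lower (adjusted p = 0.0327; adjusted p = 0.438 with an estimated correlation), a call that ended without naive replicate 1 (adjusted p = 0.0529), naive replicate 3 (0.0677) or immunized replicate 3 (0.0518), the sample with the lowest mean of this list (-0.35), and with array weights (0.0546). Of 9 osteoblast and osteocyte genes 0 passed in limma (3 lower, unadjusted; 0 adjusted over the list alone), led by Sp7 (-0.58 ± 0.18). That list missed the threshold (adjusted p = 0.0565), and passed without naive replicate 2 (0.0283) or 3 (0.0499) and without immunized replicate 1 (0.0475), 4 (0.0481) or 5 (0.00822), with an adjusted p of 0.425 to 0.542 in these settings with an estimated correlation. It also passed after quantile normalization (0.0321), with the replicate block (4.9e-04) and without both samples with joined numbers (0.0414). The same held without naive replicate 1 and immunized replicates 3 and 5 together (0.0419). With an estimated correlation the adjusted p in these further settings was 0.362 to 0.611. None of 14 osteoclast genes passed in limma (1 higher, unadjusted; 0 adjusted over the list alone), with Ostm1 at 0.36 ± 0.14. Camera's adjusted p for osteoclast genes was 0.0728, and it passed without naive replicate 1 (0.0144) or immunized replicate 2 (0.0134) or 3 (0.0332), with an adjusted p of 0.453 to 0.606 in these settings with an estimated correlation. The osteoclast list also passed with array weights (0.0205) and without naive replicate 1 and immunized replicates 3 and 5 together (0.0249). With an estimated correlation these became 0.440 and 0.567.

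In Wnt, BMP and TGF-beta signalling 1 of 31 genes rose and 3 fell (1 and 13 adjusted over the list alone). The BMP pathway inhibitor Smad6 fell (-1.09 ± 0.14), as did the ligands Bmp7 (-0.88 ± 0.16) and Wnt4 (-0.55 ± 0.14). Inhba, the activin A subunit, rose (0.42 ± 0.11), but its 2 probe sets disagreed (1.21 and -0.36). The falling one had an array below 4 (log2), and without it Inhba differed by 1.21. Of 17 hypoxia and glycolysis genes 3 fell (7 adjusted over the list alone): the oxygen sensor Egln3 (-1.01 ± 0.13), the carbonic anhydrase Car9 (-1.10 ± 0.26) and the glycolytic regulator Pfkfb3 (-0.45 ± 0.10). Both lists shifted lower, with an adjusted p of 0.438 for the signalling and 0.455 for the hypoxia list with an estimated correlation. Of 19 immediate early genes Atf3 rose (1.42 ± 0.25; 1 adjusted over the list alone), and the list shifted higher (adjusted p = 0.0221; adjusted p = 0.438 with an estimated correlation). That call ended without immunized replicate 1 (0.0752). None of 18 oxidative phosphorylation genes passed in limma (1 higher, unadjusted; 0 adjusted over the list alone), and the list did not shift (adjusted p = 0.599), its median (-0.0013) and mean (0.010) differing in sign. Over the 7 lists of bone, signalling, hypoxia, stress and respiration, 2 of 115 distinct genes rose and 9 fell (1 and 4 after quantile normalization). The number called was 4, 1 and 2 without naive replicates 1, 2 and 3, and 3, 25, 7, 6 and 5 without immunized replicates 1 to 5.

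Other lists held markers of further cell types that a dissected disc could hold. Of 9 smooth muscle and pericyte markers 2 fell (5 adjusted over the list alone), the proteoglycan gene Cspg4 (-1.13 ± 0.25) and Lmod1 (-0.47 ± 0.11). Of 7 Schwann cell markers the myelin gene Ncmap fell (-1.15 ± 0.27; 3 adjusted over the list alone). Both lists shifted lower (adjusted p = 0.438 with an estimated correlation), the Schwann cell list not without naive replicate 3 (adjusted p = 0.208) or immunized replicate 4 (0.0704). Endothelial markers shifted higher by camera (adjusted p = 0.0320; adjusted p = 0.466 with an estimated correlation), with 0 of 10 past limma's test (2 higher, unadjusted; 1, Tie1, adjusted over the list alone), and not without naive replicate 3 (0.120) or immunized replicate 4 (0.115) or with the replicate block (0.0630). Neuron and spinal cord markers shifted higher (adjusted p = 0.0320; adjusted p = 0.438 with an estimated correlation), with 0 of 10 past limma's test (2 higher, unadjusted; 0 adjusted over the list alone) and Stmn2 at 1.02 ± 0.36. That call ended without naive replicate 1 (0.0987), immunized replicate 2 (0.0510) or immunized replicate 5 (0.165), without naive replicate 1 and immunized replicates 3 and 5 together (0.0816), and with the replicate block (0.121).

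Of 7 synovial lining markers Htra4 fell (-1.24 ± 0.24; also adjusted over the list alone), and the list did not shift (adjusted p = 0.426). In limma 0 of 16 skeletal muscle genes (1 lower, unadjusted) and 0 of 9 adipocyte genes (1 lower, unadjusted) passed, and 0 in either list when adjusted over the list alone. Neither list shifted (adjusted p = 0.599 and 0.431). The skeletal muscle list had a median difference of -0.0049 and a mean of 0.038. Over the 7 lists of other cell types, 4 of 68 distinct genes fell and 0 rose in limma, with 12 lower and 5 higher at an unadjusted p under 0.05. After quantile normalization 2 fell and 0 rose, with the same unadjusted counts. The number called was 9 without immunized replicate 2 and 2 without immunized replicate 5. It was 0 without naive replicate 1, 2 or 3 or without immunized replicate 1; at an unadjusted p under 0.05 those 4 settings had 3 higher genes each and 11, 9, 7 and 9 lower genes.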

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

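Tests of carried-over bone marrow and of the spread between samples in smooth muscle and Schwann cell markers were chosen after the values were seen. So were those of inflammation as the cause of the clock gene differences and of a substrain difference at Zhx2. The other tests in this part were written down first. The rule for reading the test of Zhx2 liver targets was changed after its result was seen.

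A gap test on the 5 immunized samples was run for 175 named genes and 41 list means. Chance sets off about 1 in 20 such tests. The test was set off by 6 genes and 2 lists, no larger a share, so their gaps are only described. The share of the immunized range taken by the gap of 1 sample was 0.945 for Arl2bp, where immunized replicate 5 (1.20) lay far above the next value (-1.13). Immunized replicate 2 was lowest for Fcgr3 (share 0.718), Lyz2 (0.769) and Tlr7 (0.733), and for the plasma cell list (0.741). Immunized replicate 4 was lowest for Derl3 (0.727) and highest for Esam (0.726). Immunized replicate 3 was lowest for the bone formation list (0.718). Outside the genes tested, 246 of 10092 probe sets that name no gene or several were higher in immunized discs and 214 were lower.

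A rise of immune genes beside a fall of disc genes could come from a lower share of disc tissue in the immunized samples. If other tissues took its place, markers of every other cell type would rise alike. Yet 2 of 6 other cell type lists had a median below 0 with a 95% interval over their members that excludes 0. These were smooth muscle and pericyte (-0.41, from -0.72 to -0.038) and Schwann cell (-0.38, from -1.15 to -0.13). A share lost to immune cells would lower these lists too, so the test cannot decide about that. Nor can it decide about other tissues if disc cells also carry these markers, since a loss of disc tissue would then lower them. The smooth muscle mean was lowest in immunized replicates 3 and 5 (-0.46 and -0.54), as was the cartilage matrix mean (-0.78 and -0.73). Members vary together (estimated correlation 0.49 and 0.37), but over the samples the 95% intervals of the mean differences narrowly exclude 0 as well. These intervals were not adjusted for 6 lists. For smooth muscle the interval was -0.87 to -0.013, with the groups apart. For Schwann cell markers it was -0.93 to -0.039, with immunized replicate 2 (0.22) above naive replicate 2 (0.12). The Schwann cell median was -0.19 without naive replicate 3. These falls do not tell whether the share of disc tissue was lower. Marrow carried over with the discs is another candidate, since neutrophil and erythroid markers were both high in immunized replicates 3 and 5. With the erythroid mean as a covariate the difference in neutrophil markers was 0.634 (95% interval 0.297 to 0.972) against 0.781 before. Of the 10 measured neutrophil markers, 7 are also on other lists. The kept difference would argue against marrow as the whole cause of the neutrophil rise only if the covariate removed marrow transcripts. That also requires a ratio of neutrophil to erythroid transcripts that was alike in all samples. In that fit the bone marrow progenitor difference was kept as well, at 0.463 (0.177 to 0.749) against 0.601. The megakaryocyte difference went from 0.41 to 0.17 (-0.098 to 0.44) and that of the cell cycle from 0.43 to 0.24 (0.064 to 0.41). The covariate thus does not decide, and marrow stays open for all these lists. A response to immunization, which the design names and which includes the adjuvant, stays open, as does a change in the immune cell types themselves; neither was tested apart.

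Dbp and Nr1d1 fell together, which may reflect a difference in the time of day of tissue collection. Among 14 other clock genes, 78.6% (11) lay on the side that such a shift would give, a share in line with it (exact two-sided binomial p = 0.0574 against equal odds, genes not being independent), and the 6 that passed limma's test all did: Cry1 rose (0.86) and Per3 (-0.61), Tef (-0.88), Hlf (-0.66), Ciart (-0.38) and Bhlhe41 (-0.65) fell. The genes off that side were Npas2 (-0.23), Nr1d2 (0.11) and Per2 (0.06), and Clock counted as on it at 0.001. Arntl (0.07) and Per2, which also cycle strongly, barely differed. Inflammation as the cause cannot be told apart from collection time: the immunized sample with the lowest chemokine mean, replicate 5, lay 99.9% of the way from the naive to the immunized mean in the clock output genes, but 1 sample decides nothing and 5 are too few for a relation. No collection times were available.

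Zhx2, a transcriptional repressor chosen after its value was seen, had the lowest p of all 18193 genes, at 2.12 ± 0.15 (adjusted p = 0.00277). A difference between BALB/c substrains at Zhx2, low expression being known in BALB/cJ, cannot be told apart from an effect of immunization. The labels give only BALB/c, and the gap of 1.71 between the groups, beside a range of 0.18 in the naive and 0.73 in the immunized samples, was measured on a gene picked for its low p, where a wide gap is expected (195 genes had a gap wider than both ranges). An action of Zhx2 on 3 genes that it represses in liver is open too: 0 of 2 measured ones passed as lower in limma, which had been set down as the sign against it, but H19 was not measured and the 95% interval of Gpc3 (-1.53 to 0.31) includes a marked fall, while that of Afp (-0.022 to 0.53) leaves room for almost none.

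Only the real 1 of the 56 splits of the 8 samples gave as many genes higher (812, against 161 in the highest other split). The same held for lower genes (851, against 285). For the counts of single genes this makes chance an unlikely source. A rank of 1 in 56 cannot exclude chance, and the counts changed widely when samples were left out. The next split by total set immunized replicates 1, 3 and 5 against the rest (446 genes). For the lists, chance cannot be excluded either. Counting the real one, 4 of 56 splits gave as many lists higher (18, against 21 in the highest other split) and 28 as many lower (9, against 21). The others with as many higher set naive replicates 2 and 3 with immunized replicate 2, 3 or 5 against the rest (21, 21 and 20 lists). They share most of the real grouping, so they are not independent of it.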

How the results depend on the processing

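The erythroid covariate, the level-class settings and the omission of naive replicate 1 with immunized replicates 3 and 5 were chosen after seeing the data. Among the 1663 called genes, 0 were called in the other direction in any refitted setting, and 2 changed sign when probe sets ending in _x_at and _s_at were left out. In most of them (790 higher, 844 lower) the groups did not overlap, so leaving out samples could not have changed the sign. The number of calls changed widely between settings. Apart from settings with fewer samples, the cause was not tested. Against 812 higher and 851 lower genes, quantile normalization gave 540 and 368, array weights 2495 and 3405, an adjusted p under 0.10 gave 1631 and 2152, a change of at least 1 on the log2 scale 239 and 96, and all probe sets tested singly 1485 and 1302. The erythroid covariate gave 1287 higher genes. Leaving out naive replicate 1 with immunized replicates 3 and 5 gave 173 and 45. Leaving out both samples with joined numbers gave 0 and 0 in limma, with 1621 and 2173 at an unadjusted p under 0.05. Leaving out 1 sample gave from 17 (without naive replicate 2) to 1293 (without immunized replicate 2) higher and from 4 to 1710 lower genes. The replicate block gave 6 and 1. Deviations of samples with the same number from their group means correlated at r = -0.047, 0.243 and -0.101 for numbers 1 to 3. Only number 2 correlated best with its own. These values give no sign that the numbers pair the samples, but 3 numbers are too few to exclude it. Median centring, the trended and robust model, the _x_at and _s_at omission and both level-class settings kept both counts within 1.5 times. For the lists (18 higher, 9 lower), camera with an estimated correlation gave 0 and 0 (4 lists at an unadjusted p under 0.05) and fry 5 and 0 (14 and 8 unadjusted); the other settings kept both counts within 1.5 times. Single lists still crossed camera's threshold in some settings: bone formation, endothelium, immediate early, megakaryocyte, neuron and Schwann cell genes lost their calls, and annulus, B cell, dendritic cell, erythroid, NK cell, osteoblast, osteoclast, skeletal muscle and T cell genes gained one (adjusted p from 0.331 to 0.625 with an estimated correlation in those settings). Of 175 named genes, none reversed, which takes a changed sign and a pass in either setting. With 1 sample left out, 1040 of 1400 values kept their direction and side of the threshold, 332 lost the threshold and 28 gained it. Under the other settings the numbers were 1554, 262 and 104 of 1920. The filter on the mean level was not run because centring removed the level, so what dim signal limits is known only from the level classes.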

Other observations

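The family enrichments in this part were tested after the gene values were seen.

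Several gene families outside or only partly inside the fixed lists held more higher genes than expected. Among 312 families with at least 8 measured members, grouped by the letters that open their symbols, 8 passed Fisher's exact test in 624 tests, all for higher genes. C-type lectins led with 10 of 26 higher (adjusted p = 5.1e-05), and besides those named for their large rises they included Clec4a3 (1.78), Clec4a2 (1.30), Clec4b1 (0.88) and Clec10a (0.77). Immunoglobulin kappa variable genes had 7 of 13 higher (adjusted p = 1.5e-04), although their probe sets can bind related transcripts. Schlafen genes, which interferons induce, had 5 of 9 higher (adjusted p = 0.00237), led by Slfn4 (1.62) and Slfn8 (1.34). The Ms4a membrane proteins had 6 of 17 higher in the group of symbols that begin with Ms (adjusted p = 0.00654), led by Ms4a4c (2.12) and Ms4a6d (1.88). Interferon-inducible Ifi genes had 5 of 13 higher (adjusted p = 0.0149), led by Ifi202b (2.03) and Ifi204 (1.89). The GTPases of immune cells named Gimap had 4 of 8 higher (adjusted p = 0.0186), led by Gimap9 (0.92). Genes of one family can share probes and regulation, so the members are not independent.

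Keratins were the leading family among the lower genes, with 8 of 48 lower, but did not pass (adjusted p = 0.110). Beyond Krt19 and Krt20, Krt7 fell by 1.51 and Krt80 by 1.42 on the log2 scale. Further genes with clock links were among those with the lowest p, Nfil3 (1.30 ± 0.11, adjusted p = 0.00648), a repressor that opposes Dbp, and the deadenylase Noct (1.28 ± 0.12, adjusted p = 0.00648). Both were chosen after their values were seen, and in both all 5 immunized samples lay above all 3 naive samples.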
